A study of Mus musculus with 29 samples.

How the data were processed

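The deposited files hold raw counts of unique molecular identifiers (UMIs) per cell barcode and gene, a file for each of 29 libraries, per the file headers and the values, which are whole numbers of at least 0. The labels name neither the aligner nor the genome build or annotation, and the submitters' processing notes list no tools, so these steps are unknown here. No barcode exceeded 20.0% of counts from the 13 mitochondrial genes, which points to a filter applied before the counts were deposited. Embryonic day, tissue, GFP sort and replicate number of each library were taken from the labels. Of 23651 gene symbols over all files, 22645 matched the symbols of a mouse gene name table, and symbols are given in mouse spelling.

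Cells with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs were kept, 150903 of 176029 barcodes. A library held 2998147 to 282614121 UMIs in kept cells. Doublets were scored per library with scrublet in scanpy 1.11.5 (30 components) and left out only as an alternative. Libraries were clustered by stage, and at E8.75 the gut tube apart from the extraembryonic libraries, on counts scaled to 10000 per cell and log-transformed, with 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 1.0 (10 iterations, igraph 0.11.9). Of 159 clusters, 121 were named after a class of fixed markers. A class needed a mean log2 difference of its markers from the other clusters of at least 0.4 and of at least 0.67 of that of the best class, and at least 3 markers detected in 10% of cells. Among these, the class with most markers in the 10 top genes of the cluster gave the name. Clusters with a median UMI count under 0.33 of the library median were named only with such a marker, and clusters led by genes of other cell types were left unnamed. Marker lists were fixed beforehand, but this naming rule was set after looking at the clusters and went through several versions before any expression test was run. Unnamed clusters held 17547 cells (11.6%), on average 51.01% of cells at E3.5, 10.14% at E4.5, 2.96% at E5.5 and 25.95% at E6.5. At E7.5 the average was 17.17% in GFP-positive, 4.96% in GFP-negative and 8.41% in parietal endoderm libraries. At E8.75 it was 7.24% in GFP-positive, 5.74% in GFP-negative, 16.37% in parietal endoderm, 2.24% in yolk sac endoderm, 20.33% in anterior and 25.49% in posterior libraries.

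Counts were summed per library over the cells of interest, which makes the library the unit of replication. For sorted and dissected tissue from E7.5 on these were endoderm cells, meaning all kept cells except those of clusters named as another tissue, so that unnamed clusters stayed in, and otherwise cells of the class under study, with at least 10 such cells per library. Genes were filtered with filterByExpr and tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) on TMM-normalized counts, with Benjamini-Hochberg adjustment and a threshold of 0.05. The CPM values (counts scaled to a common library total) in the text were computed here from the deposited counts with TMM-scaled library sizes, as were the log2 fold changes, and their SE is the absolute log2 fold change over the square root of F. The 29 gene lists (8 to 24 members tested at most) were fixed before the data were examined and tested with camera of limma 3.58.1, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Where a group had no counts of a gene, the fold was computed against a floor of 3 counts over the group and given as a lower bound, which covers counting error only.

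The 14 comparisons were GFP-positive against GFP-negative endoderm at E7.5 and E8.75, their interaction with stage, the same sorts within anterior gut-like and posterior gut-like cells, anterior against posterior gut, yolk sac endoderm against GFP-positive gut, parietal endoderm against yolk sac endoderm and over time, visceral endoderm over E5.5, E6.5 and E7.5, and the 3 lineages of E3.5 and E4.5 embryos. The E8.75 comparisons of whole endoderm shared a fit over 12 libraries. Genes named in the text came from a rule fixed beforehand. It took Afp and Ttr in GFP comparisons, then the 6 largest called log2 fold changes each way among genes with at least 20 CPM in the higher group and no overlap of libraries, without predicted genes, and then up to 3 members of each list with the smallest p. The text names a part of these.

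The position of GFP-sorted cells was called with logistic regression (scikit-learn 1.9.0, C of 0.01, probability above 0.5) trained on endoderm cells of the anterior and posterior libraries with 2000 variable genes. Shares were compared with a 2-sided exact permutation test that was coded directly, and scipy 1.17.1 held the sparse count matrices.

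Each script that tests many genes was tested on simulated data with 200 changed genes per comparison, drawn from the means and library sizes of that comparison. It called 4.5% (trophoblast-like cells) to 56.7% (yolk sac against gut endoderm) of 1.5-fold changes, 26.9% to 91.0% of 2-fold changes and 86.4% to 100% of 4-fold changes in the same comparisons. Of its calls, 1.1% (primitive endoderm-like cells) to 9.9% (epiblast-like cells) were false. Of 280 unchanged gene lists, camera called 7 with the preset and 1 with the estimated correlation. The simulated genes were drawn independently of each other, so this does not test the preset on lists of correlated genes. Changed genes were taken only from those above a minimum expected count, and the variation of each gene came from a trend over expression. The rates therefore do not cover genes with few counts. Real comparisons called up to 77.8% of genes (yolk sac against gut endoderm), and normalization under such widespread change was not tested.

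Alternatives fixed beforehand were DESeq2 1.42.0 in place of edgeR, no filter on low counts, DESeq2 size factors in the edgeR test, a minimum of 3000 UMIs, doublets left out, all cells past the filter, Leiden resolution 0.5, other sets of libraries in the fit, a term for replicate number, and leaving out each library. Position was also called with cells thinned to 2000 UMIs, with 500 variable genes, with training on each replicate alone, and without genes that differ at E7.5. Chosen after seeing the data were fits without low-UMI copies of barcodes shared between libraries, fits of clusters named as endoderm only, position without genes of cells outside the endoderm, and a crossed replicate term. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.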

Results

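Single-cell RNA sequencing counted transcript molecules (unique molecular identifiers, UMIs) in cells of mouse embryos that carry an Afp-GFP transgene. Afp is expressed in visceral endoderm, an extraembryonic epithelium, so that its green fluorescent protein (GFP) marks this tissue and cells that recently came from it. The 29 libraries ran from embryonic day (E) 3.5 to E8.75. Whole embryos gave 2 libraries at E3.5, 2 at E4.5 and 3 at E5.5, and dissected visceral and parietal endoderm gave 2 at E6.5. At E7.5, endoderm sorted by GFP gave 3 libraries of GFP-positive cells, which the labels name visceral endoderm, and 3 of GFP-negative cells, which they name definitive endoderm. Parietal endoderm gave 2 libraries at E7.5 and 2 at E8.75. At E8.75 there were 2 libraries each of yolk sac endoderm, of GFP-positive and of GFP-negative gut tube cells, and of the anterior and the posterior gut tube.

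The libraries held 304 to 14085 cell barcodes, 176029 in total, and 150903 cells passed the filters (101 to 12635 per library). The kept cells of a library carried 12838806 and 16900651 UMIs at E3.5, 2998147 and 6922360 at E4.5, 54553559 to 97226519 at E5.5, and 106770935 and 121296850 at E6.5. At E7.5 the totals were 176051053 to 282614121 in GFP-positive, 125959197 to 218271188 in GFP-negative and 29080764 and 31465052 in parietal endoderm libraries. At E8.75 they were 153260371 to 230840035 in the GFP-sorted, 119283071 and 133613145 in yolk sac endoderm, 124329671 and 180095066 in parietal endoderm, and 35283070 to 50520307 in the anterior and posterior libraries. The median kept cell held 7678 to 53900 UMIs and 2132 to 6033 genes. Expression is given as CPM, the summed counts of a library scaled to a common total, as mean ± SD over libraries. The scaling was computed within the fit of each comparison, so the CPM of a gene in the same libraries can differ between comparisons. Differences are log2 fold changes ± SE, with adjusted p from edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment, and a gene with an adjusted p under 0.05 is named as called. Nothing in the labels states that replicate libraries came from separate animals or litters, so the p-values measure only the spread between libraries, which may be technical.

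Clusters of cells were named from fixed marker genes to ask what each dissection and sort contained. At E3.5, 20.6% ± 6.72 of cells were epiblast-like, 18.3% ± 9.13 primitive endoderm-like and 10.1% ± 0.23 trophoblast-like (SD, n = 2). The E4.5 libraries held 20.7% ± 1.56, 44.6% ± 12.59 and 12.3% ± 3.58 of these classes (n = 2). With a coarser clustering the E4.5 share of primitive endoderm-like cells was 27.1%, with 53.47% in replicate 1 and 0.70% in replicate 2. Visceral endoderm-like cells made up 28% ± 7.1 of E5.5 embryos (n = 3) and 49.9% ± 0.95 of the E6.5 dissection (n = 2), and 9.5% and 68.2% with the coarser clustering.

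Endoderm, counted as all cells except those of clusters named as another tissue, made up 98.6% ± 1.04 of GFP-positive cells at E7.5, and visceral endoderm-like cells 80.7% ± 3.12 (n = 3). In the GFP-negative libraries endoderm made up 22% ± 3.66, mostly definitive and gut endoderm-like cells (16.8% ± 3.49), and mesoderm-like cells 37.5% ± 0.12 (n = 3). At E8.75, 98.2% ± 0.17 of GFP-positive and 53.9% ± 1.23 of GFP-negative cells were endoderm (n = 2 each). GFP-positive cells were 34.5% ± 0.73 visceral endoderm-like, 33.2% ± 3.42 posterior gut-like, 13.4% ± 0.54 liver-pancreas-like and 9.9% ± 0.21 anterior gut-like. With the coarser clustering these shares were 47.1%, 27.2%, 8.6% and 8.1%. Anterior gut-like cells made up 39.3% ± 1.01 and posterior gut-like cells 6.3% ± 1.33 of GFP-negative cells, beside 24.8% ± 3.2 mesoderm-like and 14.5% ± 0.79 cardiomyocyte-like cells. Endoderm made up 99.6% ± 0.13 of yolk sac endoderm libraries, 50.1% ± 1.1 of anterior and 55.5% ± 1.03 of posterior gut tube libraries (n = 2 each). In parietal endoderm libraries it made up 64.2% ± 2.62 at E7.5, beside 30.6% ± 3.73 trophoblast-like cells, and 75.8% ± 1.59 at E8.75, beside 15.8% ± 0.65 erythroid-like cells. These endoderm shares include unnamed clusters, among them any led by genes of cell types outside the marker classes. Unnamed clusters held on average 20.33% of all cells in anterior, 25.49% in posterior and 16.37% in E8.75 parietal endoderm libraries. The average was 17.17% in E7.5 GFP-positive libraries and 2.24% to 8.41% in the other libraries from E7.5 on. Comparisons of dissected or sorted tissue used the summed counts of endoderm cells of each library, and those of lineages in whole embryos used the cells of that class.

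GFP-positive and GFP-negative endoderm were compared at E7.5 to ask how visceral endoderm differs from definitive endoderm as both come to cover the embryo. Afp, the gene behind the reporter, stood at 341 ± 21.5 against 2.34 ± 1.98 CPM in GFP-positive and GFP-negative cells (n = 3 each, log2 difference 7.14 ± 0.52, edgeR adjusted p 1.62e-06). The transport protein gene Ttr stood at 6525 ± 198 against 63.2 ± 22.2 CPM (6.69 ± 0.39, edgeR adjusted p 3.96e-07). The glucose transporter gene Slc2a2 (212 ± 4.32 against 1.13 ± 0.623 CPM), the apolipoprotein gene Apoc2 (37.7 ± 13.1 against 0.189 ± 0.147 CPM) and the lectin gene Lgals2 (401 ± 20.1 against 2.72 ± 0.701 CPM) were also higher in GFP-positive cells. The endocytic receptor genes Amn and Dab2 were higher by 5.99 ± 0.14 and 5.34 ± 0.14, the lysosomal protease genes Ctsh, Lgmn and Ctsl by 5.81 ± 0.16, 5.31 ± 0.13 and 4.51 ± 0.13, and the liver regulator Hnf4a by 5.81 ± 0.19. In the other direction, Pou5f1, a regulator of pluripotency, stood at 1.26 ± 0.335 against 126 ± 35.1 CPM (log2 difference -6.65 ± 0.28, edgeR adjusted p 5.99e-08). The neuronal-type gene Stmn2 (-6.71 ± 0.24), the cytoskeletal gene Ermn (-6.88 ± 0.18) and the imprinted gene Nnat (-6.25 ± 0.28) were lower in GFP-positive cells. The head and foregut regulators Otx2, Hesx1 and Hhex were lower, with log2 differences of -3.72 ± 0.12, -4.88 ± 0.20 and -2.33 ± 0.09, as were the notochord and streak gene T (-3.42 ± 0.20) and the signal gene Shh (-4.75 ± 0.29). The endoderm pioneer factor Foxa1 was lower in GFP-positive endoderm (-2.51 ± 0.09), but with all cells of each library in the sum it was not called (-0.51). The mesoderm and neural regulator Irx3 stood at 1.67 ± 0.256 against 38.1 ± 1.59 CPM.

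At E7.5, edgeR called 10773 of 15125 genes, 5240 higher and 5533 lower in GFP-positive cells, of which 6054 differed over 2-fold. Genes fixed beforehand for transport and secretion by visceral endoderm were all higher (24 higher of 24, adjusted over the list alone 24 higher, camera adjusted p 1.58e-09). Lysosome and endocytosis genes were mostly higher (18 higher, 1 lower and 1 not called of 20, adjusted over the list alone 18 higher and 1 lower, camera adjusted p 2.47e-07). Oxidative phosphorylation genes were mostly higher (13 higher and 5 not called of 18, adjusted over the list alone 13 higher, camera adjusted p 0.00693). Genes of the X chromosome or germline that are active in extraembryonic tissue were mostly higher (12 higher, 2 lower and 1 not called of 15, adjusted over the list alone 12 higher and 2 lower, camera adjusted p 0.00108), with Trap1a at 283 ± 20.6 against 4.55 ± 0.786 CPM. Definitive endoderm and streak regulators were mostly lower (1 higher, 14 lower and 2 not called of 17, adjusted over the list alone 1 higher and 14 lower, camera adjusted p 0.00693). Anterior visceral endoderm genes were mostly lower (9 lower and 1 not called of 10, adjusted over the list alone 9 lower, camera adjusted p 0.00108). Anterior gut regulators were mostly lower (1 higher, 16 lower and 2 not called of 19, adjusted over the list alone 1 higher and 17 lower, camera adjusted p 7.69e-05). Posterior gut regulators split into 9 higher and 9 lower, and with all cells in the sum into 3 and 16. Markers of other tissues were present in the GFP-negative endoderm sums. In GFP-positive against GFP-negative cells, mesoderm genes were mostly lower (2 higher, 11 lower and 2 not called of 15, adjusted over the list alone 2 higher and 11 lower, camera adjusted p 0.0384). Cardiomyocyte genes were mostly lower (9 lower and 2 not called of 11, adjusted over the list alone 9 lower, camera adjusted p 0.00715). The posterior Hox genes Hoxa7 and Hoxb7 stood at 2.74 ± 0.113 against 0.0674 ± 0.0407 CPM and 2.34 ± 0.122 against 0.0644 ± 0.0188 CPM, with 7 counts each over the GFP-negative libraries, and the cholesterol synthesis gene Sqle at 2.65 ± 0.395 against 28.2 ± 6.31 CPM. No call among these lists held with an estimated correlation (adjusted p 0.15 to 0.594).

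The same sorts were compared in the gut tube at E8.75, when cells of both origins lie in a common epithelium, to ask which differences remain. Afp stood at 161 ± 11.98 against 2.905 ± 0.675 CPM in GFP-positive and GFP-negative endoderm (n = 2 each, log2 difference 5.80 ± 0.21, edgeR adjusted p 7.87e-09). Ttr stood at 1112 ± 149 against 70.3 ± 0.108 CPM (3.98 ± 0.11) and the retinol carrier gene Rbp4 at 1155 ± 64.2 against 55.95 ± 3.63 CPM (4.37 ± 0.12). The largest called difference among the named genes was Trap1a, an X-linked gene of extraembryonic tissue and tumours, at 121 ± 2.69 against 0.214 ± 0.114 CPM (log2 difference 9.04 ± 0.18, edgeR adjusted p 1.48e-10). The X-linked homeobox gene Rhox5 (188 ± 8.05 against 4.27 ± 1.21 CPM) and the cell cycle inhibitor gene Cdkn2a (48.4 ± 0.568 against 0.702 ± 0.104 CPM) were also higher in GFP-positive cells. Xlr5a was higher by 7.18 ± 0.15, but Xlr and Rhox genes have near-identical copies among which counting could split reads, so their values are uncertain. Lgals2 (6.05 ± 0.16), the apolipoprotein gene Apoe (3.17 ± 0.09), and the endoderm regulators Hnf4a (3.88 ± 0.15), Foxa3 (2.75 ± 0.09) and Gata6 (1.67 ± 0.08) were higher too. The hindgut regulator Cdx2 and the enteric gene Tlx2 were higher by 1.59 ± 0.10 and 2.04 ± 0.21. Lower in GFP-positive cells were the heart and pharynx regulator Nkx2-5 (0.804 ± 0.121 against 46.4 ± 7.297 CPM, log2 difference -5.85 ± 0.16, edgeR adjusted p 1.14e-09) and the foregut regulator Nkx2-3 (1.6 ± 0.163 against 71.7 ± 0.196 CPM). The same direction held for Hoxb1 (-4.02 ± 0.23), Vgll2 (-4.47 ± 0.32), Otx2 (-3.70 ± 0.24) and Isl1 (-2.22 ± 0.08), which mark anterior gut or pharynx. Pou5f1 (-4.69 ± 0.33) and the mesenchyme gene Foxc1 (-3.28 ± 0.14) were lower as well. The naming rule left clusters led by germ cell genes unnamed, so any such cells stayed in the endoderm sums. RNA of germ cells is therefore not separated here from Pou5f1 of gut cells.

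**Figure D1:**
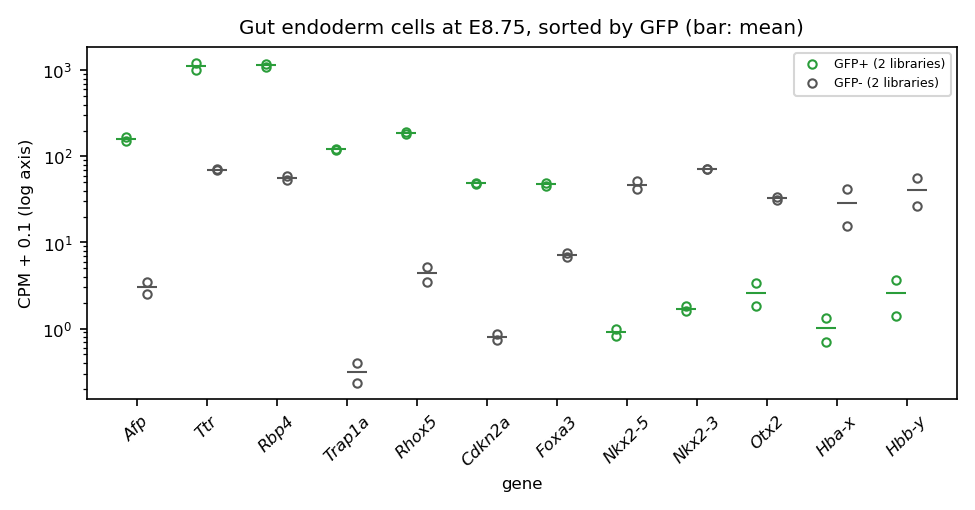
Expression of 12 genes in endoderm of the GFP-sorted gut tube at E8.75 (CPM with 0.1 added, log axis), with a point for each of 2 libraries per sort and a bar at the mean. Trap1a shows the widest gap, 121 ± 2.69 against 0.214 ± 0.114 CPM, while Hba-x and Hbb-y vary most between the GFP-negative libraries.

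At E8.75, edgeR called 7141 of 17452 genes, 3440 higher and 3701 lower in GFP-positive cells, and 2801 differed over 2-fold. When only the libraries of this comparison were fitted, 3755 genes were called and 58.8% of them, against 48.2%, were higher. Visceral endoderm transport genes were mostly higher (23 higher and 1 lower of 24, adjusted over the list alone 23 higher and 1 lower, camera adjusted p 6.74e-20). Lysosome genes were mostly higher (17 higher and 3 not called of 20, adjusted over the list alone 17 higher, camera adjusted p 2.86e-10), and regulators common to all endoderm all higher (15 higher of 15, adjusted over the list alone 15 higher, camera adjusted p 7.12e-12). Anterior gut regulators were mostly lower (1 higher, 21 lower and 1 not called of 23, adjusted over the list alone 1 higher and 21 lower, camera adjusted p 3.11e-12). Posterior gut regulators were mostly higher (17 higher, 2 lower and 4 not called of 23, adjusted over the list alone 17 higher and 2 lower, camera adjusted p 0.00311). Liver and pancreas genes were mostly higher (9 higher, 2 lower and 1 not called of 12, adjusted over the list alone 9 higher and 2 lower, camera adjusted p 0.00311). Genes of the X chromosome or germline were mostly higher (11 higher, 2 lower and 2 not called of 15, adjusted over the list alone 12 higher and 2 lower, camera adjusted p 3.71e-08). Cholesterol synthesis genes were mostly lower (1 higher, 10 lower and 8 not called of 19, adjusted over the list alone 1 higher and 10 lower, camera adjusted p 0.0303), but only 2 were lower when the other libraries were left out of the fit. Among markers of other tissues, mesoderm genes were mostly lower (15 lower and 3 not called of 18, adjusted over the list alone 15 lower, camera adjusted p 6.38e-09). Erythroid genes were mostly lower (1 higher, 8 lower and 3 not called of 12, adjusted over the list alone 1 higher and 8 lower, camera adjusted p 0.00841), and the embryonic globin genes Hba-x and Hbb-y, which have near-identical relatives, stood at 0.904 ± 0.436 against 28.5 ± 18.5 CPM and 2.46 ± 1.62 against 40.8 ± 20.7 CPM. Genes induced by tissue dissociation were mostly higher (10 higher and 4 not called of 14, adjusted over the list alone 11 higher, camera adjusted p 2.36e-05), with the stress factor gene Atf3 at 116 ± 22.4 against 26.7 ± 1.89 CPM. The calls that held with an estimated correlation (adjusted p in brackets) were those of visceral endoderm transport (0.0294), lysosome (0.0294), core endoderm (0.025), anterior gut (0.0122), liver and pancreas (0.0458), X chromosome or germline (0.0426) and mesoderm (0.0433) genes, and the other lists had 0.097 to 0.304.

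A term for the interaction of stage and sort asked whether the GFP difference itself changed between E7.5 and E8.75. The endocytic receptor gene Lrp2 stood at 209 ± 3.99 CPM in GFP-positive and 7.44 ± 2.07 CPM in GFP-negative endoderm at E7.5 (n = 3 each), and at 5.604 ± 0.493 and 12.5 ± 0.163 CPM at E8.75 (n = 2 each). Its log2 difference dropped by 5.97 (SE 0.26, edgeR adjusted p 7.76e-08). Dab2, at 1603 ± 59.4 CPM in GFP-positive cells at E7.5, was at 54.4 ± 3.55 CPM at E8.75, and the carbonic anhydrase gene Car7 and the ligand gene Apln passed from called higher to called lower in GFP-positive cells (interaction -7.68 ± 0.23 and -7.27 ± 0.17). In the other direction, the channel gene Kcnk2 was lower in GFP-positive cells at E7.5 (0.123 ± 0.00874 against 2.71 ± 0.0597 CPM) and higher at E8.75 (21.96 ± 1.303 against 6.21 ± 0.172 CPM, interaction 6.29 ± 0.17, edgeR adjusted p 1.26e-08). Shh (5.58 ± 0.32), T (4.64 ± 0.28), Foxa1 (3.4 ± 0.18), Hhex (2.96 ± 0.13) and the epithelial keratin gene Krt8 (2.17 ± 0.19) also passed from called lower to called higher. Trap1a stood at 4.72 ± 0.821 and 0.201 ± 0.106 CPM in GFP-negative cells of the earlier and later stage, and at 313 ± 23.7 and 116 ± 2.45 CPM in GFP-positive cells. Its difference widened by 3.03 ± 0.29. Hoxa7 stood at 80.7 ± 3.79 CPM in GFP-positive and 35.99 ± 2.76 CPM in GFP-negative cells at E8.75, and its difference narrowed (-4.29 ± 0.29), as did that of Hoxb7 (-4.39 ± 0.31), which was not called with all cells in the sum (-0.99).

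The interaction was called for 9316 of 17159 genes, 4738 with a higher and 4578 with a lower value at E8.75. Of 14788 genes tested at both stages, 5221 were higher in GFP-positive cells at E7.5. Of these, 3891 (74.5%) had a called interaction toward 0 or past it, and 70 moved away from 0. Among the 5480 lower genes, 3740 (68.2%) moved toward 0 or past it and 45 away. Together 3662 of these genes had the other sign at E8.75, of which 1423 were called that way. Choosing genes by their E7.5 call tilts this balance toward 0, since the interaction uses the same libraries. Of the 4175 genes called both at E8.75 and in the interaction, a choice that tilts the other way, 3030 had a smaller and 1145 a larger absolute difference at E8.75 than at E7.5. Over the genes tested at both stages, the median absolute log2 difference was 0.76 at E7.5 and 0.30 at E8.75. Across genes, which are not independent replicates, the differences of the stages had a Pearson correlation of 0.469 and a Spearman correlation of 0.335. Genes higher at both stages numbered 1751, where independent lists would share 1080, and 717 were higher at E7.5 and lower at E8.75, where 1165 would be. Visceral endoderm transport genes were mostly lower (20 lower and 4 not called of 24, adjusted over the list alone 21 lower, camera adjusted p 5.18e-07). Oxidative phosphorylation genes were mostly lower (15 lower and 3 not called of 18, adjusted over the list alone 15 lower, camera adjusted p 0.000728). Definitive endoderm and streak regulators were mostly higher (13 higher and 4 not called of 17, adjusted over the list alone 14 higher, camera adjusted p 0.000519). Notochord genes were all higher (8 higher of 8, adjusted over the list alone 8 higher, camera adjusted p 0.00121). With an estimated correlation the adjusted p of these lists was 0.208 to 0.513, and no call held.

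**Figure D2:**
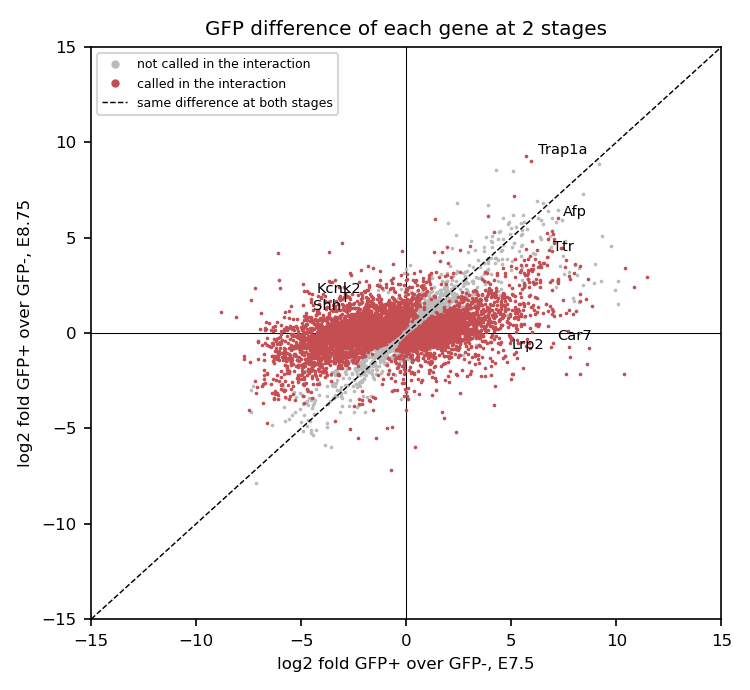
Log2 fold of GFP-positive over GFP-negative endoderm at E7.5 (horizontal axis) and at E8.75 (vertical axis), with a point per gene, red where the interaction was called. The median absolute log2 difference was 0.76 at E7.5 and 0.30 at E8.75, and the least squares slope of the E8.75 on the E7.5 difference was 0.227.

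The sorts were next compared within anterior gut-like and within posterior gut-like cells of the same GFP-sorted libraries, to ask which differences at E8.75 remain within a class. The classes are not matched in position, since the posterior regulators Cdx2 (2.28 ± 0.30) and Hoxc4 (1.95 ± 0.16) were higher in GFP-positive anterior gut-like cells. Afp stood at 22.8 ± 3.63 against 0.609 ± 0.184 CPM in anterior gut-like and 33.3 ± 1.17 against 1.34 ± 0.0814 CPM in posterior gut-like cells of the GFP-positive and GFP-negative sort (n = 2 each). Trap1a differed by 10.45 ± 0.36 in the anterior (edgeR adjusted p 0.000142) and by 10.47 ± 0.36 in the posterior class (edgeR adjusted p 0.000383). Rhox5 (5.63 ± 0.22 and 8.20 ± 0.18), Cdkn2a (7.14 ± 0.24 and 7.56 ± 0.32), Ttr (3.26 ± 0.16 and 4.37 ± 0.23) and Rbp4 (3.51 ± 0.16 and 3.26 ± 0.14) were also higher in GFP-positive cells of both classes. In anterior gut-like cells Xlr5a was higher by 7.75 ± 0.30, with the same doubt about its copies, and Foxa3 by 2.63 ± 0.20. The lung and thyroid regulator Nkx2-1 stood at 0.736 ± 0.0143 against 12.5 ± 1.69 CPM there and Nkx2-5 at 4.72 ± 0.979 against 63.8 ± 7.87 CPM, and Hhex was lower (-1.85 ± 0.14). In posterior gut-like cells the hindgut regulator Cdx4 stood at 30.8 ± 4.004 against 190 ± 3.34 CPM and the posterior Hox gene Hoxc10 at 32.1 ± 11.7 against 103 ± 28.5 CPM, both lower in GFP-positive cells. The cholesterol synthesis gene Idi1 (-0.94 ± 0.12) was lower there too, as was Nkx2-5 (-5.15 ± 0.41) with the heart muscle gene Tnnt2 (-3.75 ± 0.30). The GFP-negative libraries hold cardiomyocyte-like cells, so RNA of heart cells is not separated here from a difference of gut cells. The globin gene Hbb-y was lower in GFP-positive cells of both classes (-4.81 ± 0.44 and -3.71 ± 0.60), and Atf3 was higher (2.29 ± 0.16 and 1.23 ± 0.15). The mesenchyme regulator Foxf1 was lower (-2.78 ± 0.35 and -4.42 ± 0.32), and in the anterior class it was not called without GFP-positive replicate 2 (-2.66) or without doublets (-1.59).

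In anterior gut-like cells 1341 of 14273 genes were called, 890 higher and 451 lower. This count was 515 without GFP-positive replicate 1 and 435 without GFP-positive replicate 2. With a term for replicate number, a pairing that stays open here, it was 3829. In posterior gut-like cells 631 of 14174 genes were called, 397 higher and 234 lower, with 300 without GFP-positive replicate 2, 1270 without GFP-negative replicate 1 and 1179 without GFP-negative replicate 2. Without a filter on low counts it was 1115, and with the term for replicate number 2693. The list of visceral endoderm transport genes was mostly higher (19 higher, 1 lower and 2 not called of 22, adjusted over the list alone 20 higher and 1 lower, camera adjusted p 1.57e-15) in the anterior class, and mostly higher (16 higher, 1 lower and 6 not called of 23, adjusted over the list alone 20 higher and 2 lower, camera adjusted p 4.37e-13) in the posterior class. Genes of the X chromosome or germline were mostly higher (10 higher and 3 not called of 13, adjusted over the list alone 11 higher, camera adjusted p 6.48e-12) in the anterior class, and mostly higher (11 higher and 2 not called of 13, adjusted over the list alone 11 higher, camera adjusted p 4.37e-13) in the posterior class. Anterior gut regulators were in part lower (10 lower and 13 not called of 23, adjusted over the list alone 1 higher and 17 lower, camera adjusted p 2.99e-08) in the anterior class. Core endoderm regulators were mostly higher (13 higher and 2 not called of 15, adjusted over the list alone 14 higher, camera adjusted p 1.04e-10) there, where 5 were higher without GFP-positive replicate 2. Mesoderm genes were mostly lower (13 lower and 3 not called of 16, adjusted over the list alone 15 lower, camera adjusted p 4.67e-11) in the anterior class, with 3 lower without that library. These list calls did not hold with an estimated correlation (adjusted p 0.167 to 0.3).

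Anterior and posterior gut tube endoderm was compared to find genes of position, which then served to place the GFP-sorted cells. The heart and pharynx regulator Nkx2-5 stood at 45.2 ± 2.51 against 0.102 ± 0.00604 CPM in anterior and posterior endoderm (n = 2 each, log2 difference 8.78 ± 0.28, edgeR adjusted p 1.31e-08). Otx2 (30.9 ± 0.0314 against 0.175 ± 0.0973 CPM), Nkx2-3 (82.95 ± 3.32 against 1.35 ± 0.709 CPM), Hhex (29.3 ± 1.603 against 3.95 ± 0.557 CPM) and the foregut regulator Sox2 (65.5 ± 3.08 against 14.6 ± 2.63 CPM) were higher in anterior cells. The posterior Hox genes Hoxa9 and Hoxb9 had no counts in anterior cells and stood at 38.5 ± 0.453 and 32.04 ± 0.287 CPM in posterior cells. They were at least 583-fold and 486-fold lower in anterior cells, taking 3 counts over the group as the floor. Hoxc9 (-8.50 ± 0.31), Cdx2 (-3.35 ± 0.12) and T (-3.34 ± 0.25) were lower in anterior endoderm as well. The germ cell and early embryo gene Dppa3 had no counts in anterior and stood at 26.0 ± 11.3 CPM in posterior endoderm. RNA of germ cells in the posterior sums is therefore not excluded. Genes of the visceral endoderm comparison also differed by position, with Rhox5 at 27.9 ± 0.7202 against 183 ± 4.77 CPM, Trap1a at 19.5 ± 0.0215 against 115 ± 2.03 CPM, Apoe at 121 ± 0.516 against 462 ± 46.8 CPM and Amn at 4.75 ± 0.105 against 33.6 ± 5.44 CPM. The immediate early gene Egr1, which tissue dissociation induces, stood at 44.4 ± 2.15 against 135 ± 4.997 CPM. The heart muscle genes Myl4 (5.20 ± 0.47) and Tnnt2 (4.35 ± 0.34) and the mesenchyme gene Foxc1 (3.56 ± 0.19) were higher in anterior sums, so RNA of heart and mesenchyme cells is not separated here from genes of position such as Nkx2-5.

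Here 4319 of 17452 genes were called, 1951 higher and 2368 lower in anterior endoderm, and 1802 differed over 2-fold. Leaving out anterior replicate 1 or 2 gave 2712 or 2734 called genes, and leaving out posterior replicate 1 or 2 gave 2789 or 2736. Anterior gut regulators were mostly higher (22 higher and 1 lower of 23, adjusted over the list alone 22 higher and 1 lower, camera adjusted p 3.41e-17). Posterior gut regulators were mostly lower (1 higher, 21 lower and 1 not called of 23, adjusted over the list alone 1 higher and 21 lower, camera adjusted p 1.7e-15). Genes of visceral endoderm transport were mostly lower (23 lower and 1 not called of 24, adjusted over the list alone 23 lower, camera adjusted p 7.85e-17). Genes of the X chromosome or germline were mostly lower (12 lower and 3 not called of 15, adjusted over the list alone 12 lower, camera adjusted p 4.75e-08). Dissociation genes were mostly lower (9 lower and 5 not called of 14, adjusted over the list alone 10 lower, camera adjusted p 1.7e-07). Cardiomyocyte genes were mostly higher (8 higher, 2 lower and 1 not called of 11, adjusted over the list alone 8 higher and 2 lower, camera adjusted p 0.00378). The calls that held with an estimated correlation (adjusted p in brackets) were those of anterior gut (0.00441), posterior gut (0.0368), visceral endoderm transport (0.0368) and X chromosome or germline (0.0368) genes, and the other lists had 0.0531 to 0.182.

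A classifier trained on anterior and posterior cells was applied to the GFP-sorted endoderm to ask where cells of each origin lie along the gut tube. It called 64.61% ± 2.48 of GFP-positive and 14.71% ± 0.28 of GFP-negative cells posterior (SD, n = 2 each), 49.9 percentage points apart. Both GFP-positive libraries (66.37% and 62.85%) lay above both GFP-negative libraries (14.51% and 14.91%), and the 2-sided exact permutation p was 0.33, the smallest that 2 libraries per group can give. Trained on either replicate alone, it assigned 92.8% to 96.1% of the cells of the other replicate to their own dissection. Without the genes called between the sorts at E7.5, the difference was 52.08 points. The genes with the most weight toward anterior included Myl7, Crabp2 and Actc1, of which Myl7 and Actc1 are heart muscle genes. Without genes of the cells outside the endoderm the difference was 49.97 points. Each cell had to be called anterior or posterior, although 34.5% of GFP-positive cells were visceral endoderm-like and 13.4% liver-pancreas-like. The training cells included unnamed clusters, which held 20.33% of all cells in anterior and 25.49% in posterior libraries. The training libraries also differed in genes of the GFP comparison, such as Trap1a (19.5 against 115 CPM in anterior and posterior endoderm). Genes that differ between the sorts at E8.75 were not left out, so position and origin are not fully separated.

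**Figure D3:**
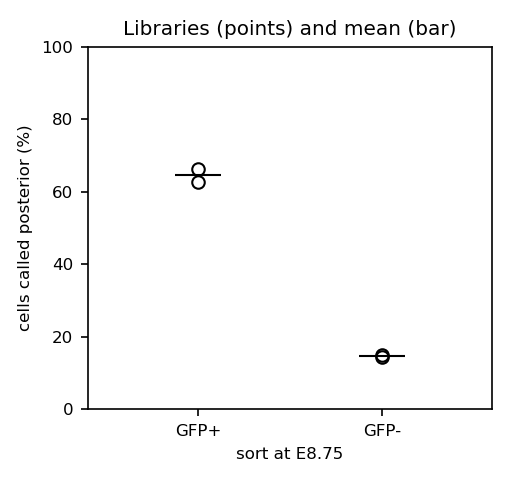
Share of GFP-positive and GFP-negative endoderm cells at E8.75 called posterior (percent of cells), with a point for each library and a bar at the mean. The GFP-positive libraries sit at 66.37% and 62.85% and the GFP-negative libraries at 14.51% and 14.91%.

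Yolk sac endoderm and GFP-positive gut endoderm, which both descend from visceral endoderm, were compared at E8.75 to ask what distinguishes extraembryonic from embryonic visceral endoderm derivatives. The water channel gene Aqp8 stood at 193 ± 12.3 against 0.09998 ± 0.00701 CPM in yolk sac and GFP-positive gut endoderm (n = 2 each, log2 difference 10.90 ± 0.14, edgeR adjusted p 2e-12). Lrrc19 (9.93 ± 0.28), the ion transport regulator Fxyd2 (8.93 ± 0.31), Slc2a2 (7.30 ± 0.15), Dab2 (5.01 ± 0.10), Lgmn (4.76 ± 0.09) and Hnf4a (4.58 ± 0.12) were also higher in yolk sac endoderm, as was Trap1a (643 ± 20.98 against 121 ± 2.69 CPM). The respiratory chain gene Cox5a stood at 1724 ± 8.33 against 424 ± 14.02 CPM. Shh stood at 0.0712 ± 0.00522 against 76.5 ± 16.6 CPM (log2 difference -10.05 ± 0.24, edgeR adjusted p 2.42e-11), and the signal gene Fgf8 (-9.80 ± 0.35), T (-9.42 ± 0.36), Hoxc9 (-8.83 ± 0.26), Hoxd9 (-7.94 ± 0.22), Isl1 (-8.33 ± 0.15) and Foxa1 (-3.98 ± 0.13) were lower in yolk sac endoderm. The dissociation-induced genes Fos and Egr1 were lower there (-3.90 ± 0.11 and -4.07 ± 0.08).

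Here 13577 of 17452 genes were called, 6458 higher and 7119 lower in yolk sac endoderm, and the median log2 difference of all genes was -0.11. Among visceral endoderm transport genes the calls were all higher (24 higher of 24, adjusted over the list alone 24 higher, camera adjusted p 1.35e-11). Lysosome genes were mostly higher (17 higher, 1 lower and 2 not called of 20, adjusted over the list alone 17 higher and 1 lower, camera adjusted p 1.59e-06). Oxidative phosphorylation genes were all higher (18 higher of 18, adjusted over the list alone 18 higher, camera adjusted p 1.65e-06). Anterior gut regulators were mostly lower (1 higher, 21 lower and 1 not called of 23, adjusted over the list alone 1 higher and 21 lower, camera adjusted p 4e-06). Posterior gut regulators were all lower (23 lower of 23, adjusted over the list alone 23 lower, camera adjusted p 9.63e-08). Liver and pancreas genes were mostly lower (1 higher, 10 lower and 1 not called of 12, adjusted over the list alone 1 higher and 10 lower, camera adjusted p 0.00922). The calls that held with an estimated correlation (adjusted p in brackets) were those of oxidative phosphorylation (0.0401) and anterior gut (0.0462) genes, and the other lists had 0.079.

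Parietal endoderm, which lays down the basement membrane next to the trophoblast, was compared with yolk sac endoderm at E8.75 to set the extraembryonic endoderm tissues apart. The basement membrane collagen genes Col4a1 and Col4a2 stood at 20790 ± 143 against 249 ± 19.9 CPM and 7454 ± 14.3 against 105 ± 2.52 CPM in parietal and yolk sac endoderm (n = 2 each, log2 differences 6.38 ± 0.11 and 6.15 ± 0.11, edgeR adjusted p 1.41e-12 and 1.37e-12). The linker protein gene Nid1 (2334 ± 0.0925 against 2.75 ± 0.209 CPM), the activin inhibitor gene Fst (1938 ± 53.9 against 0.06099 ± 0.00448 CPM), the thrombin receptor gene Thbd (188 ± 4.63 against 0.174 ± 0.0414 CPM) and the endoderm regulator Sox7 (286 ± 3.95 against 3.63 ± 0.00841 CPM) were higher in parietal endoderm. Wfdc1 and the growth factor gene Fgf3 had no counts in yolk sac endoderm and stood at 152 ± 4.15 and 111 ± 1.96 CPM in parietal endoderm, at least 7300-fold higher for Fgf3. The secreted protein genes Spp2 (-10.71 ± 0.17) and Fgg (-8.45 ± 0.14), Apoe (-6.47 ± 0.11) and the epithelial junction genes Cldn7 (-6.66 ± 0.10) and Cdh1 (-5.93 ± 0.10) were lower in parietal endoderm, as was the respiratory chain gene Uqcrc1 (-1.32 ± 0.06). Blood genes were present in the parietal endoderm sums, with the leukocyte gene Ptprc at 16.7 ± 1.58 CPM and no counts in yolk sac endoderm, and the globin gene Hbb-bs, which has near-identical copies, at 63.4 ± 20.1 against 0.382 ± 0.0866 CPM.

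Here 13342 of 17452 genes were called, 6981 higher and 6361 lower in parietal endoderm. Parietal endoderm and basement membrane genes were mostly higher (20 higher and 1 lower of 21, adjusted over the list alone 20 higher and 1 lower, camera adjusted p 1.88e-08). The transport list of visceral endoderm was all lower (24 lower of 24, adjusted over the list alone 24 lower, camera adjusted p 1.23e-11). Oxidative phosphorylation genes were mostly lower (17 lower and 1 not called of 18, adjusted over the list alone 17 lower, camera adjusted p 3.73e-05). Erythroid genes were all higher (12 higher of 12, adjusted over the list alone 12 higher, camera adjusted p 0.000319). No call among these lists held with an estimated correlation (adjusted p 0.0713 to 0.308).

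Parietal endoderm was compared between E8.75 and E7.5 to follow this tissue over time. Col4a1 stood at 18660 ± 76.5 against 6759 ± 508 CPM at E8.75 and E7.5 (n = 2 each, log2 difference 1.47 ± 0.21, edgeR adjusted p 0.00512), but was not called without E8.75 replicate 1 (1.48) or replicate 2 (1.47). The proliferation gene Mki67 rose (402 ± 11.8 against 65.6 ± 5.32 CPM), as did the histone gene Hist1h1d (152 ± 0.387 against 2.15 ± 0.341 CPM), whose family has near-identical copies. The epithelial-mesenchymal regulator Snai1 fell (111 ± 0.831 against 282 ± 5.09 CPM), as did Krt19 (-2.14 ± 0.15) and the glycolysis gene Gapdh (-1.21 ± 0.11). Genes of neighbouring cells changed too. The trophoblast genes Plac1 (-3.46 ± 0.31) and Hand1 (-3.06 ± 0.16), the vascular peptide gene Adm (-5.48 ± 0.32) and the macrophage gene Tyrobp (-4.23 ± 0.30) fell. The uterine natural killer cell gene Gzmg stood at 0.299 ± 0.423 against 66.6 ± 66.2 CPM with close copies in its family. The globin genes Hbb-y and Hba-x rose to 364 ± 41.2 and 373 ± 5.24 CPM.

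Between these stages 7482 of 13803 genes were called, 4009 higher and 3473 lower at E8.75. Without E8.75 replicate 1 or 2 the counts were 3829 and 3815, the latter with 64.1% higher against 53.6%. Trophoblast genes were mostly lower (9 lower and 5 not called of 14, adjusted over the list alone 9 lower, camera adjusted p 0.00248). Erythroid genes were mostly higher (9 higher, 2 lower and 1 not called of 12, adjusted over the list alone 9 higher and 2 lower, camera adjusted p 0.0389). Oxidative phosphorylation genes were in part lower (9 lower and 9 not called of 18, adjusted over the list alone 12 lower, camera adjusted p 0.00516). Of the visceral endoderm transport genes, 16 were lower without E7.5 replicate 2 and 15 higher without E7.5 replicate 1, so no direction is given for them. With an estimated correlation the adjusted p of these lists was 0.544 to 0.732, and no call held.

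Visceral endoderm-like cells were followed from whole E5.5 embryos to the E6.5 dissection and on to GFP-positive cells at E7.5, to trace how the tissue changes before gut formation. Between E5.5 and E6.5 the calcium carrier gene S100g stood at 542 ± 21.6 against 17.6 ± 2.46 CPM at E6.5 and E5.5 (n = 2 and 3, log2 difference 4.96 ± 0.13, edgeR adjusted p 2.07e-07). Rbp4 (4193 ± 226 against 245 ± 56.9 CPM), Apoe (5791 ± 29.6 against 712 ± 54.7 CPM), Ttr (6270 ± 254 against 926 ± 29.98 CPM) and the lipid carrier gene Fabp1 (108 ± 0.459 against 5.73 ± 2.401 CPM) rose as well, as did the respiratory chain gene Sdhb (1.77 ± 0.08). The germ cell and early embryo gene Dppa3 fell (0.225 ± 0.0287 against 33.8 ± 11.7 CPM, -7.18 ± 0.36, edgeR adjusted p 1.16e-06), as did the neural regulator Sox3 (-5.33 ± 0.30), the pluripotency gene Utf1 (-1.73 ± 0.11) and the sterol synthesis gene Sqle (-3.22 ± 0.16). The E5.5 cells came from whole embryos, which hold epiblast, and the E6.5 cells from dissected endoderm, so RNA of epiblast cells in the E5.5 suspension is not separated from a fall within visceral endoderm. The dissociation genes Atf3 (3.69 ± 0.42) and Fos (2.21 ± 0.33) rose. The anterior visceral endoderm regulators Otx2 (-5.30 ± 0.26), Sfrp1 (-4.93 ± 0.40), Fzd5 (-3.91 ± 0.16) and Hhex (-1.91 ± 0.21) were called lower at E6.5 in clusters of the main resolution. With the coarser clustering, in which the E5.5 class held fewer and the E6.5 class more cells, Otx2 was not called (-0.09) and Sfrp1 (0.45), Fzd5 (0.19) and Hhex (0.12) changed sign. The direction of these anterior genes therefore stays open.

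From E5.5 to E6.5, 8168 of 14631 genes were called, 4271 higher and 3897 lower at E6.5. Visceral endoderm transport genes were mostly higher (22 higher, 1 lower and 1 not called of 24, adjusted over the list alone 22 higher and 1 lower, camera adjusted p 1.27e-07). Oxidative phosphorylation genes were mostly higher (17 higher and 1 not called of 18, adjusted over the list alone 17 higher, camera adjusted p 3.22e-06). Cholesterol synthesis genes were mostly lower (16 lower and 3 not called of 19, adjusted over the list alone 1 higher and 16 lower, camera adjusted p 7.78e-06). Epiblast and ectoderm genes were all lower (11 lower of 11, adjusted over the list alone 11 lower, camera adjusted p 4.15e-05). Anterior visceral endoderm genes were all lower (11 lower of 11, adjusted over the list alone 11 lower, camera adjusted p 1.54e-06), but with the coarser clustering 6 were called higher. From E6.5 to E7.5, 1808 of 14631 genes were called, 997 higher and 811 lower at E7.5. Leaving out E6.5 replicate 1 or 2 gave 327 or 460 called genes, and leaving out E7.5 replicate 1 or 2 gave 696 or 716. DESeq2 gave 3122, and the coarser clustering 3275. The hormone precursor gene Trh rose to 138 ± 2.13 CPM from 2.08 ± 0.316 CPM (n = 3 and 2, log2 difference 6.05 ± 0.15, edgeR adjusted p 9.34e-08), and the peptide gene Apela (4.01 ± 0.44) and Krt19 (3.12 ± 0.18) rose too. Otx2 was called higher (1.59 ± 0.23), and lower with the coarser clustering (-1.44). The streak genes Mixl1 (1.52 ± 0.0732 against 17.7 ± 0.249 CPM), Fgf8 (-3.85 ± 0.26) and Tdgf1 (-6.40 ± 0.45), the pluripotency genes Dppa5a (-2.03 ± 0.10) and Fgf5 (-2.48 ± 0.30) and the matrix gene Has2 (-2.20 ± 0.12) fell. The E6.5 cells came from a dissection, and the E7.5 cells from a GFP sort summed over all endoderm. At E6.5 the mesoderm and streak genes Mesp1 and T stood at 5.60 ± 1.65 and 2.34 ± 0.106 CPM. RNA of streak or epiblast cells in the E6.5 suspension is thus not separated from a fall within visceral endoderm. Epiblast and ectoderm genes were mostly lower (7 lower and 4 not called of 11, adjusted over the list alone 10 lower, camera adjusted p 2.14e-08). Egr1 was called lower (-1.29 ± 0.24), but not without E6.5 replicate 1 (-1.28) or 2 (-1.30). These list calls did not hold with an estimated correlation (adjusted p 0.106 to 0.323).

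Epiblast-like, primitive endoderm-like and trophoblast-like cells were compared between E4.5 and E3.5 to follow the lineages of the blastocyst through implantation. In epiblast-like cells the signalling effector gene Lef1 had no counts at E3.5 and stood at 173 ± 28.6 CPM at E4.5, at least 386-fold higher (n = 2 each). The formative pluripotency genes Pou3f1 (96.8 ± 13.4 against 0.5603 ± 0.165 CPM at E4.5 and E3.5, log2 difference 7.19 ± 0.35, edgeR adjusted p 1.91e-06), Dnmt3b (3.47 ± 0.16) and Otx2 (3.86 ± 0.23) rose, as did Trh (4.29 ± 0.29) and the glycolysis genes Eno1 (3.50 ± 0.22) and Pkm (1.87 ± 0.13). The naive pluripotency genes Nanog (7.03 ± 1.45 against 235 ± 19.9 CPM, -5.13 ± 0.24, edgeR adjusted p 1.8e-06), Klf4 (-4.02 ± 0.20), Tfcp2l1 (-3.44 ± 0.21) and Dppa3 (-3.69 ± 0.23) fell. The dissociation genes Egr1 (2.44 ± 0.42) and Ier3 (3.05 ± 0.56) rose. So did the primitive endoderm genes Cubn (28.7 ± 29.2 against 0.673 ± 0.325 CPM) and Dab2 (33.6 ± 27.0 against 1.90 ± 0.183 CPM), while Gata6 fell (-3.02 ± 0.44). Some RNA of primitive endoderm cells in the E4.5 sums is therefore not excluded. Spic had no counts at E4.5, at least 79.6-fold lower. Here 3151 of 8711 genes were called, 1602 higher and 1549 lower, with 1829 by DESeq2, 1819 without E3.5 replicate 1 and 1672 without E3.5 replicate 2. Formative pluripotency genes were all higher (11 higher of 11, adjusted over the list alone 11 higher, camera adjusted p 7.4e-08). Naive pluripotency genes were mostly lower (10 lower and 3 not called of 13, adjusted over the list alone 10 lower, camera adjusted p 3.23e-05). Glycolysis and hypoxia genes were all higher (16 higher of 16, adjusted over the list alone 16 higher, camera adjusted p 7.89e-08). No call among these lists held with an estimated correlation (adjusted p 0.289 to 0.331).

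In primitive endoderm-like cells the protease inhibitor gene Spink1 stood at 1068 ± 55.9 against 1.01 ± 0.504 CPM at E4.5 and E3.5 (n = 2 each, log2 difference 10.23 ± 0.30, edgeR adjusted p 2.1e-06). The endocytic receptor genes Lrp2 (8.54 ± 0.30), Dab2 (5.92 ± 0.19), Cubn (5.51 ± 0.25) and Amn (4.49 ± 0.20) rose, with the glycolysis gene Ldha (4.81 ± 0.18) and the sterol synthesis gene Cyp51 (3.36 ± 0.21). The dissociation genes Egr1 (1.98 ± 0.30) and Fosb (4.83 ± 0.74) rose as well. Dppa3 (-5.05 ± 0.24), Tdgf1 (-6.12 ± 0.46) and Pou5f1 (-2.32 ± 0.17) fell, and Nanog had no counts at E4.5, at least 37.7-fold lower. Here 3485 of 9082 genes were called, 1748 higher and 1737 lower, with 1993 without E3.5 replicate 2. The list of visceral endoderm transport genes was all higher (11 higher of 11, adjusted over the list alone 11 higher, camera adjusted p 5.09e-09). Cholesterol synthesis genes were mostly higher (18 higher and 1 not called of 19, adjusted over the list alone 18 higher, camera adjusted p 5.09e-09). Primitive endoderm regulators were mostly higher (14 higher, 2 lower and 2 not called of 18, adjusted over the list alone 14 higher and 2 lower, camera adjusted p 1.37e-05). Basement membrane genes were mostly higher (14 higher and 4 not called of 18, adjusted over the list alone 14 higher, camera adjusted p 2.42e-06). With an estimated correlation the adjusted p of these lists was 0.244 to 0.46, and no call held.

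In trophoblast-like cells Ldha stood at 1185 ± 312 against 7.98 ± 1.43 CPM at E4.5 and E3.5 (n = 2 each, log2 difference 7.17 ± 0.34, edgeR adjusted p 6.79e-06). The glucose transporter gene Slc2a1 (4.65 ± 0.37), the trophoblast genes Elf5 (4.34 ± 0.31) and Plac1 (4.43 ± 0.34) and the signal gene Bmp4 (5.76 ± 0.48) rose. So did the dissociation genes Fos (2.89 ± 0.48), Junb (2.02 ± 0.38) and Fosb (3.93 ± 0.64), the last not called without E3.5 replicate 1 (3.56). The trophectoderm regulator Cdx2 (68.8 ± 21.6 against 662 ± 32.03 CPM), Pou5f1 (-5.44 ± 0.30) and Dppa3 (-6.33 ± 0.55) fell. The endoderm genes Gata6 (-4.06 ± 0.48), Lrp2 (-3.22 ± 0.40) and Dab2 (-2.94 ± 0.37) fell too. At E3.5 Lrp2 and Dab2 stood at 271 ± 48.0 and 265 ± 9.81 CPM in trophoblast-like cells. In primitive endoderm-like cells of that stage they stood at 2.2 ± 1.2 and 28.9 ± 0.24 CPM. This argues against RNA of those cells as the source of Lrp2 and Dab2. Dppa3 stood at 1602 ± 164 CPM at E3.5, near its level in epiblast-like (1690 ± 112 CPM) and primitive endoderm-like cells (1452 ± 59.9 CPM). RNA of those cells would have to make up most of the trophoblast-like sums, which argues against it as the main source of Dppa3. For Gata6 and Pou5f1, RNA of inner cell mass lineages in the E3.5 sums is not separated from a fall within trophoblast-like cells. Krt8 was not called (1260 ± 240 against 1316 ± 92.3 CPM), and its log2 difference of -0.06 became 0.15 without E4.5 replicate 2. Eomes was called higher (0.86 ± 0.25, edgeR adjusted p 0.0321) but not without E3.5 replicate 1 (0.61) or E4.5 replicate 1 (0.65), nor by DESeq2 (0.86). Here 1748 of 6963 genes were called, 843 higher and 905 lower, with 991 by DESeq2 and 1017 without E3.5 replicate 1. Glycolysis and hypoxia genes were mostly higher (11 higher, 2 lower and 1 not called of 14, adjusted over the list alone 11 higher and 2 lower, camera adjusted p 0.00016). Naive pluripotency genes were mostly lower (6 lower and 2 not called of 8, adjusted over the list alone 6 lower, camera adjusted p 0.00109). The shallowest of these sums held 542242 UMIs, and 26.9% of simulated 2-fold differences were called in this comparison. With an estimated correlation the adjusted p of the lists was 0.284, so their calls did not hold.

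**Figure D4:**
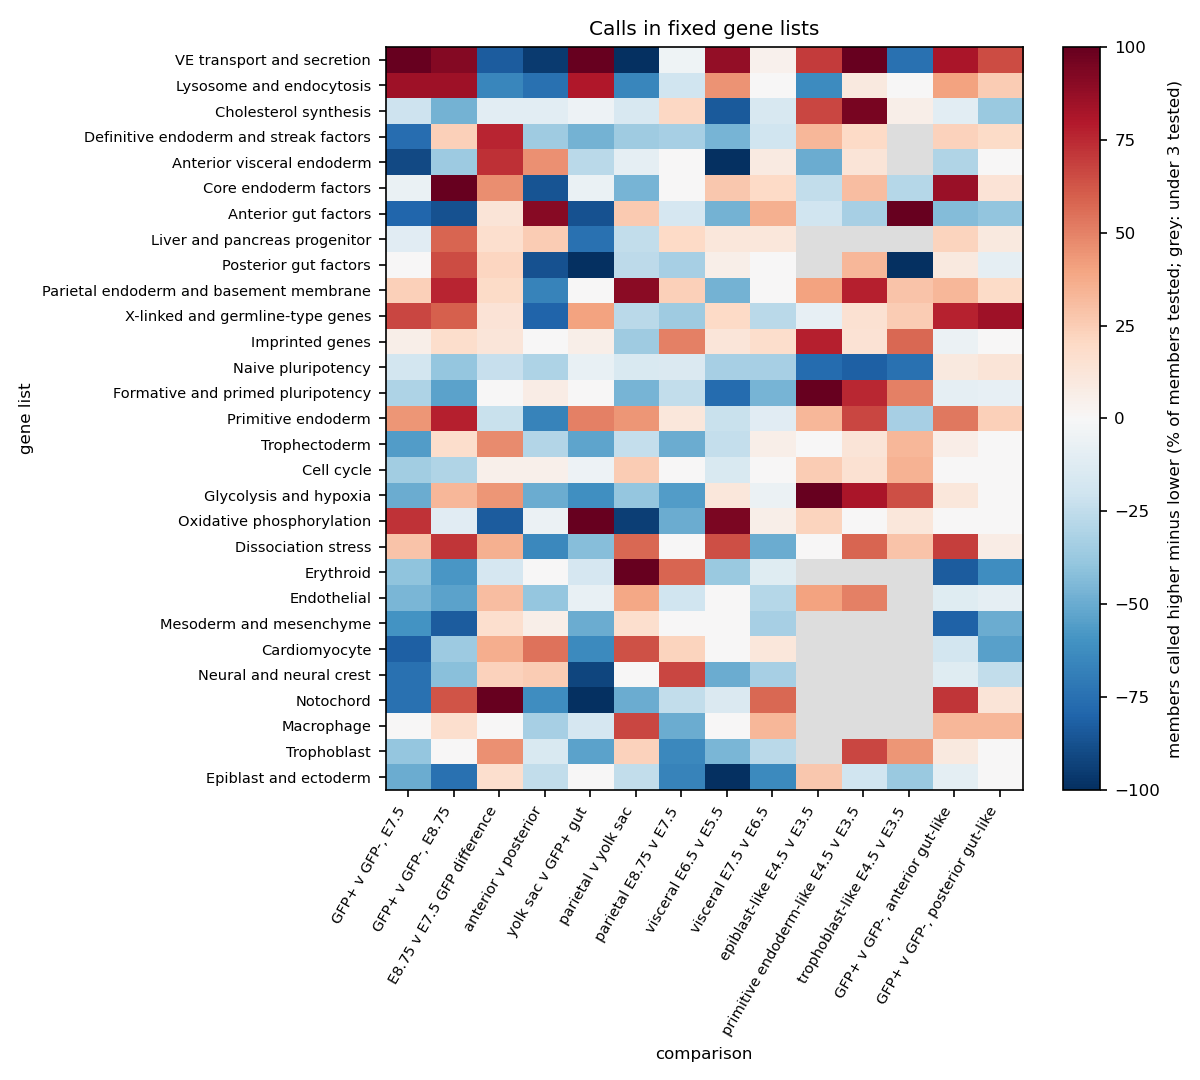
Balance of calls in 29 fixed gene lists (vertical axis) over 14 comparisons (horizontal axis), as members called higher minus members called lower in percent of those tested, on a scale from blue (lower) to red (higher). Visceral endoderm transport genes range from 24 of 24 higher in GFP-positive endoderm at E7.5 to 24 of 24 lower in parietal against yolk sac endoderm.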

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

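All tests of explanations in this part were chosen after the results they concern were seen, while the interaction of stage and sort was planned. That interaction marked 9316 genes whose GFP difference changed between E7.5 and E8.75. The log2 difference of GFP-positive from GFP-negative endoderm rose for Kcnk2 by 6.29 (SE 0.17, edgeR adjusted p 1.26e-08), Shh by 5.58 (SE 0.32), T by 4.64 (SE 0.28), Foxa1 by 3.4 (SE 0.18), Hhex by 2.96 (SE 0.13) and Krt8 by 2.17 (SE 0.19). It fell for Car7 (-7.68, SE 0.23, edgeR adjusted p 1.52e-08), Apln (-7.27, SE 0.17), Lrp2 (-5.97, SE 0.26), Dab2 (-4.66, SE 0.16) and Lgmn (-4.12, SE 0.17). Ttr (-2.77, SE 0.31), Lgals2 (-1.23, SE 0.29, edgeR adjusted p 0.00404) and Hnf4a (-2, SE 0.28) also fell toward a smaller difference, and Pou5f1 rose toward 0 by 1.9 (SE 0.45, edgeR adjusted p 0.00456). The difference of Trap1a widened by 3.03 (SE 0.29). Hoxa7 (-4.29, SE 0.29) and Hoxb7 (-4.39, SE 0.31) rested at E7.5 on 7 counts each over the GFP-negative libraries, and Hoxb7 was not called when all cells were summed (-0.99).

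The first pattern is that 7631 genes had a GFP difference at E7.5 that a called interaction moved toward 0 or past it at E8.75. Of these, 3662 had the other sign at E8.75, with 1423 called that way. The choice of genes by their E7.5 call favours this direction, but of the 4175 genes called at E8.75 and in the interaction, 3030 had a smaller and 1145 a larger absolute difference at E8.75. Sorted cells of the other kind at E8.75 would need to make up a median of 99.2% of the RNA of GFP-negative sums, or 98.7% of that of GFP-positive sums, and 84.4% or 79.6% for the genes that kept their sign. The 10 genes most restricted to GFP-positive cells stood in GFP-negative sums at a median of 2.04% of their GFP-positive level. For the 10 genes most restricted to GFP-negative cells the median in GFP-positive sums was 6.09%. Both lie far below the shares needed, which argues against mixing in the sort as the cause. Cells of unnamed clusters in the E7.5 sums do not account for it either. Over all genes tested at each stage, sums of clusters named as endoderm gave a median absolute log2 difference of 0.81 at E7.5. The main sums gave 0.77 at E7.5 and 0.35 at E8.75. RNA of mesoderm and other cells in the suspension of the E7.5 GFP-negative sort is not removed by this choice of clusters and stays open. Of the 10 splits of the 6 E7.5 libraries, 1, the real one, called 10773 genes, and the highest of the others called 0 by edgeR, with 13 to 197 genes at an unadjusted p under 0.05, and so few splits cannot give a share under 0.05. What also stays open is a difference of library preparation between the stages, which the stage confounds. A change of the tissue sampled stays open too, since the labels name visceral endoderm at E7.5 and gut tube at E8.75. Visceral endoderm transport genes, mostly lower in the interaction, were all higher in yolk sac endoderm than in GFP-positive gut. The sorts at E8.75 further differed in the share of cells called posterior (64.61% and 14.71%). A convergence of visceral and definitive endoderm in the gut tube is another hypothesis for genes that kept their sign. It does not cover those called the other way. No test here separates these explanations.

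The second pattern is the high level of genes of the X chromosome or germline in GFP-positive endoderm at E8.75, where 11 of the list were called higher. Yolk sac endoderm cells or their RNA would have to make up 14.9% (Rhox5) or more, and a median of 32.6%, of the GFP-positive RNA. The visceral endoderm transport genes, abundant in yolk sac endoderm, reached a median of 3.1% of their yolk sac level, with an upper quartile of 6.4% and a highest value of 16.2% (Spink1), which argues against this source. The ratio of Y-linked expression of GFP-positive to GFP-negative cells was 1.07 (57.8 and 54 CPM), which argues against a difference in sex. Within anterior gut-like and posterior gut-like cells the median log2 differences of the list's called genes were 5.59 and 5.71, against 4.52 in all endoderm, and posterior over anterior endoderm gave a median of 2.55, exceeded by the GFP difference for 9 of the 11 genes. These genes were chosen as called higher in the same libraries, which favours large differences within the classes. Most tested members of the whole list were also called higher within each class. A surplus of posterior cells alone therefore does not account for most of the called genes, although the classes are not matched in position. A lasting mark of visceral endoderm origin is a hypothesis that these values leave open and that was not tested further.

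The third pattern is the lower level of erythroid genes in GFP-positive endoderm at E8.75, with the globin genes Hba-x at 0.904 ± 0.436 against 28.5 ± 18.5 CPM and Hbb-y at 2.46 ± 1.62 against 40.8 ± 20.7 CPM. The sort on GFP would leave blood cells, which do not descend from visceral endoderm, in the GFP-negative fraction, although their GFP was not measured here. In the GFP-negative libraries the ratio of erythroid CPM of posterior to anterior gut-like cells was 1.02 and 1.01, a like level in cells of different position, and 70.5% to 86.3% of these cells held a count. The 5% of cells with the most counts held at most 21.1% of them, where an even spread would give 14.8%. This argues against doublets of gut and blood cells as the main source in the GFP-negative libraries, but the counts were somewhat more concentrated than even. The values are consistent with RNA of blood cells in the suspension of the GFP-negative sort (ratio 1.02), which may also carry RNA of the mesoderm and heart cells found in those libraries. A difference of the gut cells themselves was not tested.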

How the results depend on the processing

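Of 199 alternative counts of called genes, 171 stayed within 1.5 times the main count, 21 were lower and 7 higher. The fits without low-UMI copies of shared barcodes, the fits of clusters named as endoderm, the position call without genes of cells outside the endoderm and the crossed replicate term were chosen after seeing the data. Where a count moved without fewer libraries or genes to explain it, the cause was not tested.

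The E8.75 GFP comparison called 3755 genes in a fit of its own libraries, which leaves fewer degrees of freedom. DESeq2 called 3122 genes from E6.5 to E7.5 in visceral endoderm, 1829 in epiblast-like and 991 in trophoblast-like cells. Leiden resolution 0.5 gave 3275 from E6.5 to E7.5, and no filter on low counts gave 1115 in posterior gut-like cells. In primitive endoderm-like cells Leiden resolution 0.5 left 1 cell of E4.5 replicate 2, so that fit held 3 libraries.

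Without a library each, where a lone library was assumed to vary like the other groups, the counts ranged as follows. They were 9727 to 10529 for GFP at E7.5, 6286 to 7062 at E8.75, 8505 to 9357 for the interaction, 2712 to 2789 for anterior against posterior gut, 12419 to 13208 for yolk sac against gut and 12275 to 12560 for parietal against yolk sac endoderm. They were 3815 to 9578 for parietal endoderm over time, 6151 to 9067 for visceral endoderm at E6.5 against E5.5 and 327 to 1863 at E7.5 against E6.5. In epiblast-like, primitive endoderm-like and trophoblast-like cells they were 1672 to 3566, 1993 to 3267 and 1017 to 2104, and in anterior and posterior gut-like cells 435 to 1849 and 300 to 1270. Fewer libraries also mean fewer degrees of freedom.

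The replicate block gave 1011 genes for visceral endoderm at E7.5 against E6.5, 3829 in anterior gut-like cells (56.4% higher, against 66.4%) and 2693 in posterior gut-like cells. The other block counts stayed within 1.5 times: 11254 and 7363 for GFP at E7.5 and E8.75, 10200 for the interaction, 4258 for anterior against posterior, 13690 and 13402 for yolk sac and parietal endoderm, 6670 for parietal endoderm over time, 7068 for visceral endoderm at E6.5, and 2641, 3298 and 1587 for the E4.5 lineages. Same-numbered E7.5 libraries correlated at 0.088, 0.17 and 0.42 in their deviations, and 2 of 6 samples correlated best with their own number, so the numbers are not taken to pair samples. At E8.75 the GFP sorts correlated at 0.477, and at 0.412 and 0.416 within anterior and posterior gut-like cells, but 2 numbers per group cannot settle a pairing, which stays open there. With crossed numbers the epiblast-like block called 3407 genes against 2641.

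Of 60 alternative class shares 11 moved by more than 1 SD of the libraries, under Leiden resolution 0.5: 27.1% for primitive endoderm at E4.5, 9.5% and 68.2% for visceral endoderm at E5.5 and E6.5, 8.1% and 37.7% for anterior gut in GFP-positive and GFP-negative cells, 27.2%, 47.1% and 8.6% for posterior gut, visceral endoderm-like and liver-pancreas-like GFP-positive cells, 13.3% for GFP-negative cardiomyocytes, 69.4% for E7.5 parietal and 52.2% for anterior endoderm. The posterior share differed by 46.84 to 53.06 points over its alternatives.

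The 230 gene differences named in the text, counted per comparison, had 3311 alternative values, of which 3293 kept their call, 13 (8 genes) lost it, 8 of them without a library, and 5 changed sign. At Leiden resolution 0.5 Sfrp1 (0.45), Fzd5 (0.19) and Hhex (0.12) from E5.5 to E6.5 and Otx2 (-1.44) from E6.5 to E7.5 changed sign, where the named E5.5 and E6.5 cells differed. Krt8 in trophoblast-like cells, not called, was -0.27 to 0.15 without a library.

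In simulated counts 4.5% of 1.5-fold and 26.9% of 2-fold changes were called in trophoblast-like cells, the fewest of all comparisons, against 56.7% and 91.0% for yolk sac against gut endoderm.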

Other observations

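The values in this part were computed after the data were seen. Xist stood at 602 and 620 CPM in the anterior and 704 and 579 CPM in the posterior gut tube libraries, and at 40.3 to 60.7 CPM in the GFP-sorted libraries of the same stage. Y-linked genes summed to 37.2 to 46.3 CPM in the former and 48.2 to 63.3 CPM in the latter. The former trained the call of position that was applied to the latter, and what this difference between them does to the posterior shares was not tested.

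Of the 406 pairs of libraries, 28 shared more than 5 times the median number of barcodes. In parietal endoderm replicate 1 at E8.75, 3669 kept cells (30.8%) had a barcode that another library held with at least 5 times as many UMIs, and in all libraries 4136 kept cells (2.74%) did. Replicates of a group had a Pearson correlation of log2 CPM of 0.970 to 0.9996 across genes.

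Composition differed between replicates of a sort. Erythroid-like cells made up 10.24%, 9.29% and 0.61% of the E7.5 GFP-negative libraries, and notochord-like cells 6.67%, 6.43% and 12.81%. Erythroid genes stood at 64.1 and 65.1 CPM in anterior and posterior gut-like cells of E8.75 GFP-negative replicate 1, and at 139.4 and 140.9 CPM in replicate 2. In the GFP-positive libraries they stood at 4.4 to 12.5 CPM.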
